A study of Mus musculus with 8 samples.

How the data were processed

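The data were single-cell transcriptomes of 8 mouse libraries made with the 10x Genomics 3' v3.1 chemistry, which tags each captured transcript with a cell barcode and a UMI. The deposited values are UMI counts per gene and cell barcode, which the authors made with Cell Ranger 6.0.2 against mm10, per the submitters' processing notes. The release of the gene annotation is not given in the sources used here. Each library had a matrix of 32285 genes by its called cell barcodes. Gene IDs were compared with GENCODE vM21, an annotation of GRCm38: 32158 IDs were found there, 31436 of them with the same name, and coordinates of named genes are those of that annotation, counted from 1. Human samples that the series' description mentions are not analysed here. Libraries were grouped by the labels into spleens (n = 2), 1-week explants (n = 4) and 2-week explants (n = 2) of 2 mice, and the labels tie each library to its mouse.

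Cells with at least 500 UMIs, at least 300 genes and under 10% mitochondrial UMIs were kept, 11718 of 13180 barcodes. The mitochondrial limit removed 12.5% and 3.62% of the barcodes of the spleens and 1.08% to 10.9% of those of the explants. Scrublet, run within scanpy 1.11.5 with an expected share of doublets that grows with the number of cells, called 39 cells (0.333%), which is too few for it to have worked. Its calls were removed as planned, which left 11679 cells, and other treatments of doublets were run as alternatives. Counts were scaled per cell and log-transformed, 2000 variable genes and 30 principal components were used, and cells were clustered with the Leiden method on 15 neighbours at resolution 1.0 (leidenalg 0.10.2, igraph 0.11.9). Clusters were named by markers fixed before the data were examined, and a class is called B-like, T-like and so on. The markers were fixed but the scoring rule was not: 3 forms of the naming score were tried, each changed after the clusters and the shares per library had been seen. The first was a mean log2 difference from the average cluster with a margin of 1.0, the second the level of the markers as a fraction of that of the highest cluster, and the third, used here, added a minimum scaled level of 0.5 in that highest cluster. A class needed at least 3 markers detected in 0.1 of the cells and a lead of 0.1 over the next class. The other 2 forms were run as alternatives, since they change the B-like or the myeloid-like share. Granzyme-led clusters whose leading genes went against their best class stayed unnamed.

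Counts were summed per library and class, since cells are not replicates, for classes with at least 20 cells in a library, and tested with edgeR 4.0.16 (R 4.3.3; filterByExpr, TMM, glmQLFit and glmQLFTest) in 1 fit over the 8 libraries with mouse and stage as factors and 4 residual degrees of freedom. The difference of the 1-week change between mice was tested in a fit of 5 group means with 3 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method at 0.05, and each SE is the absolute log2 fold change divided by the square root of the F statistic. The pairing of libraries by mouse comes from the labels, since libraries of a mouse share an animal. Across 10710 genes the difference between mice in spleens had a correlation of 0.297 with that in 1-week explants. Replicate explants differed by more than counting noise, with a chi-square of 2.08, 9.16 and 8.19 per degree of freedom for the 3 pairs.

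Gene lists, 38 in all, were fixed before the data were examined and tested with camera of limma 3.58.1 at a preset correlation of 0.01 for lists with at least 5 tested genes, and again with an estimated correlation and with fry. A list is said to pass by camera at the preset correlation, and fry tests a list without setting it against other genes. The same lists were tested in T-like, myeloid-like and plasma-like cells, tests that were added later. Genes named for B-like cells were, per comparison, the 12 largest rises and the 12 largest falls among genes past the threshold with a mean log2 CPM of at least 5 that moved the same way in every explant library. Immunoglobulin segments, mitochondrial and ribosomal genes, unnamed gene models and markers of other classes were left out. For T-like and myeloid-like cells 8 and 8 were named by the same rule, up to 4 per list were named by smallest adjusted p, and Bcl2, Mki67, Bcl6, Cd79a and Cd74 were always given for B-like cells. Some genes that these rules choose are not reported here. Genes at 0 counts in a group have a lower bound against a floor of 3 counts over the group, and genes with 1 to 3 counts a ratio with an exact 95% counting interval. Shares of single libraries have exact binomial 95% intervals (scipy 1.17.1), and for a share of 0 the limit given is 3 counts of the total. All cover counting error only.

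Shares were compared by exact two-sided permutation of stage within mouse, with 9 arrangements. To compare shares of cells with G2M transcripts, each cell was thinned to 2000 UMIs and shallower cells were left out, 128 and 123 B-like cells of the spleens and 5 to 20 of each 1-week explant. V gene similarity, compared between the explants of the mice by an exact two-sided permutation test with 15 arrangements that was added after the values were seen, used the UMIs of Ighv, Igkv and Iglv genes in B-like and plasma-like cells, 2441 to 31673 per explant. Free RNA, transcripts of other cells that enter a droplet, was estimated per library as the level of marker genes in a class that lacks them, relative to that in all cells, as the median of 3 marker sets. For 2 lists in T-like cells the set of B-cell genes in T-like cells was also used alone, a choice made after the data were seen. Another set, macrophage genes in B-like cells, was tried first and dropped after its values were seen. The share of a gene's level that free RNA could give follows from that estimate. For a gene set of macrophages in 2-week B-like cells, a prediction on free RNA was written, run and then taken out of the tested explanations after its value was seen, because only a few patterns are weighed. Its value, 100%, is given as a measurement.

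The edgeR tests of genes, but not those of lists or shares, were tried on simulated counts with 200 changed genes. Counts were drawn from negative binomial distributions with the real libraries' gene means, sizes and estimated dispersions. The changed genes were drawn only from genes above a minimum mean count, so the rates do not hold for genes with low counts. In B-like cells at 1 week, over 10710 genes, 23.9%, 70.1% and 97.0% of changes of 1.5-, 2- and 4-fold were recovered, and in T-like cells, over 9668 genes, 29.9%, 74.6% and 97.0%. In myeloid-like cells, over 9260 genes, it was 1.49%, 5.97% and 63.6%, and for the difference between mice, over 10710 genes, 4.48%, 29.9% and 75.8%. False calls were 11 of 138 in B-like cells at 1 week, 5 of 123 from 1 to 2 weeks and 11 of 128 at 2 weeks against spleen. They were 8 of 142 in T-like cells, 6 of 53 in myeloid-like cells and 6 of 79 for the difference between mice. Alternatives planned before the data were examined were DESeq2 1.42.0, no low-count filter, no mouse block, other limits on mitochondrial UMIs, no doublet removal, another resolution, a class per cell, equal numbers of cells, gene classes left out and each library left out in turn. The other forms of the naming score, the other doublet treatments, the fits without the 2-week explants or without 1 or 2 clusters, the removal of genes attributable to free RNA and all alternatives for the plasma-like share were added after the data were seen. The labels name no library batch, and none was modelled.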

Results

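Transcripts were counted in single cells from 2 vavP-Bcl2 mice on a C57BL/6 background. In this transgenic strain BCL2, an inhibitor of apoptosis, is driven in blood cells, and the strain serves as a model of follicular lymphoma. The mice were 47 and 43 weeks old (mouse 1 and mouse 2). Cells of each spleen were compared with cells of tissue explants, made by chopping spleen, setting it in hydrogel inserts and culturing it in medium with 0.2 micrograms/ml of human BAFF, a survival factor for B cells. Each mouse gave 1 spleen library and 2 explant libraries after 1 week of culture. Mouse 2 gave 2 more explant libraries after 2 weeks, so that 8 libraries were compared. The series concerns lymphoma explants that are meant to keep the make-up of the tumour in culture, and the comparisons ask which cells and transcripts of the spleen were found in the explants. The files held 13180 cell barcodes, from 440 in explant 1 of mouse 1 to 3367 in the spleen of mouse 2, with 3918833 to 28114085 unique molecular identifiers (UMIs) per library. After filtering 11679 cells remained. Their median depth was 4149 and 4223 UMIs per cell in the spleens and 6523 to 7559 in the explants. Mitochondrial transcripts were a median 5.14% and 5.24% of the UMIs of spleen cells and 2.79% to 3.85% of those of explant cells. Explants of the same mouse and stage came from 1 animal, so p-values rest on 2 animals and partly measure the spread between explants.

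B-like cells were the most frequent class in the spleens and in the 1-week explants, and T-like cells the most frequent in the 2-week explants. The B-like share averaged 51.9% ± 4.31 (SD, n = 2) in spleens, 51.3% ± 8.00 (SD, n = 4) in 1-week explants and 29.2% ± 0.350 (SD, n = 2) in 2-week explants. T-like cells made up 23.2% ± 0.964 (SD, n = 2), 28.5% ± 3.38 (SD, n = 4) and 40.1% ± 5.23 (SD, n = 2) at these stages. These shares leave out granzyme-led clusters without a class name, whose best-scoring class was T, 6.17% and 5.98% of the cells of the 2-week explants. Plasma-like cells, the antibody-secreting class, made up 2.39% ± 0.399 (SD, n = 2), 8.12% ± 5.02 (SD, n = 4) and 13.6% ± 3.68 (SD, n = 2). Myeloid-like cells, which pool macrophage-, monocyte- and neutrophil-like clusters, made up 12.9% ± 3.37 (SD, n = 2), 10.1% ± 4.51 (SD, n = 4) and 9.14% ± 0.712 (SD, n = 2). The 2-week explants all came from mouse 2, whose 1-week explants averaged 50.2% B-like and 31.4% T-like cells, and their shares were not tested.

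**Figure D1:**
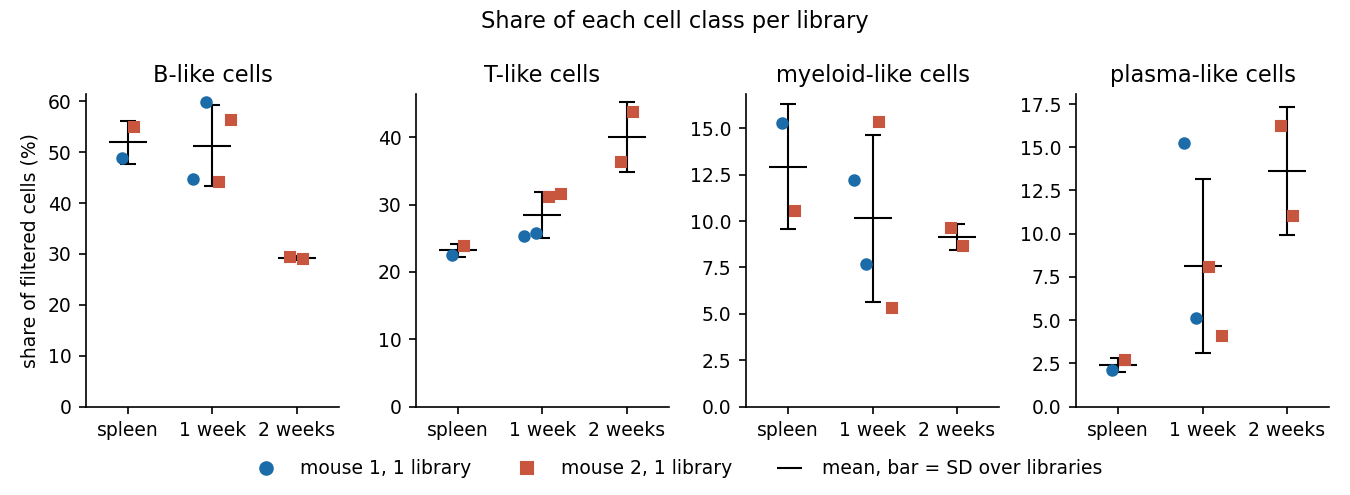
Share of filtered cells (%, vertical axis) in the B-like, T-like, myeloid-like and plasma-like classes for each library of the spleens, 1-week and 2-week explants; points are libraries, coloured by mouse, and bars give the mean and SD over libraries. The 2-week libraries lie at 29.5% and 29.0% for B-like cells, below every spleen and 1-week library, which lie between 44.1% and 59.9%.

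Relative to the spleen of the same mouse, the T-like share of the 1-week explants was higher by 5.24 percentage points (SD 2.60, higher in 4 of 4 explants). An exact two-sided permutation test within mouse gave p = 0.111, the smallest p that its 9 arrangements allow. The difference was 3.35 points at resolution 2.0 (exact permutation p = 0.222), where 3 of 4 explants were higher, and 3.00 points without the spleen of mouse 2. For plasma-like cells, a class added to the comparison after the data were seen, the mean difference was 5.72 points (SD 5.18, higher in 4 of 4 explants, exact permutation p = 0.222), and 3.26 points without the first 1-week explant of mouse 1. The B-like share differed by -0.633 points (SD 9.23, higher in 2 of 4 explants, exact permutation p = 1.0). The myeloid-like share differed by -2.78 points (SD 5.40, higher in 1 of 4 explants, exact permutation p = 0.667). Both differences were smaller than the spread between explants. Erythroid-like cells were 8.22% and 5.26% of the spleen libraries and at most 0.557% of any explant as observed, after red cells had been lysed. An observed share of 0 allows up to 0.815%, in the first 1-week explant of mouse 1. Shares are of all filtered cells, so fewer erythroid-like cells alone raise the other shares, and part of the T-like difference follows from this. By explant that difference was 2.74 and 3.26 points in mouse 1 and 7.29 and 7.66 points in mouse 2. The spleen of mouse 1 held 384 T-like and 140 erythroid-like cells of 1704, and that of mouse 2 held 732 and 161 of 3063. The small differences of mouse 1 are thus the most open to this effect. No test was run on shares among the remaining cells. With a limit of 5% mitochondrial UMIs the B-like difference turned to 19.4 points, where the spleen B-like shares were 22.6% and 33.5%, and the myeloid-like difference was -9.95 points. With the second naming score the latter was -5.21 points. Other ways of naming cells turned the sign of the B-like and myeloid-like differences, as did leaving out the first 1-week explant of either mouse (0.505 and 2.77 points) or the spleen of mouse 2 (3.49 points) for B-like cells.

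In B-like cells, 1 week of culture went with higher transcript levels of metallothioneins and of genes of glycolysis and the response to low oxygen, and with lower levels of germinal centre genes. The metallothioneins, which bind metal ions, rose most among genes with a mean log2 CPM of at least 5. Mt2 (ENSMUSG00000031762, chromosome 8, 94172664 to 94173568, plus strand, GRCm38) rose by 9.62 (SE 0.35) on the log2 scale, with an adjusted p = 3.2e-10 in edgeR's quasi-likelihood test. Its neighbour Mt1 (chromosome 8, 94179082 to 94180327, plus strand) rose by 8.00 (SE 0.25). All 27 tested genes of the glycolysis and hypoxia list rose, 27 adjusted over the list alone, with a median log2 change of 2.02. The list had an adjusted p = 6.26e-86, and an adjusted p = 0.0499 with an estimated correlation. Free RNA in the droplets could give 8.04% of the level of its median member. Among its genes were Pgk1, a glycolytic kinase (chromosome X, 106187100 to 106203699, plus strand; 3.00, SE 0.17), the lactate exporter Slc16a3 (5.43, SE 0.35), the prolyl hydroxylase P4ha1 (2.38, SE 0.16) and Ankrd37 (2.19, SE 0.15). Genes that also rose were Bnip3 (3.46), Hilpda (3.42), Ero1l (3.09), the glycolytic enzymes Tpi1 (2.72) and Aldoa (2.56), the cytokine Mif (2.55) and Hk2, the first enzyme of glycolysis (2.36). The transcription factor Bhlhe40 (2.79) and Rilpl2 (2.66) rose as well.

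**Figure D2:**
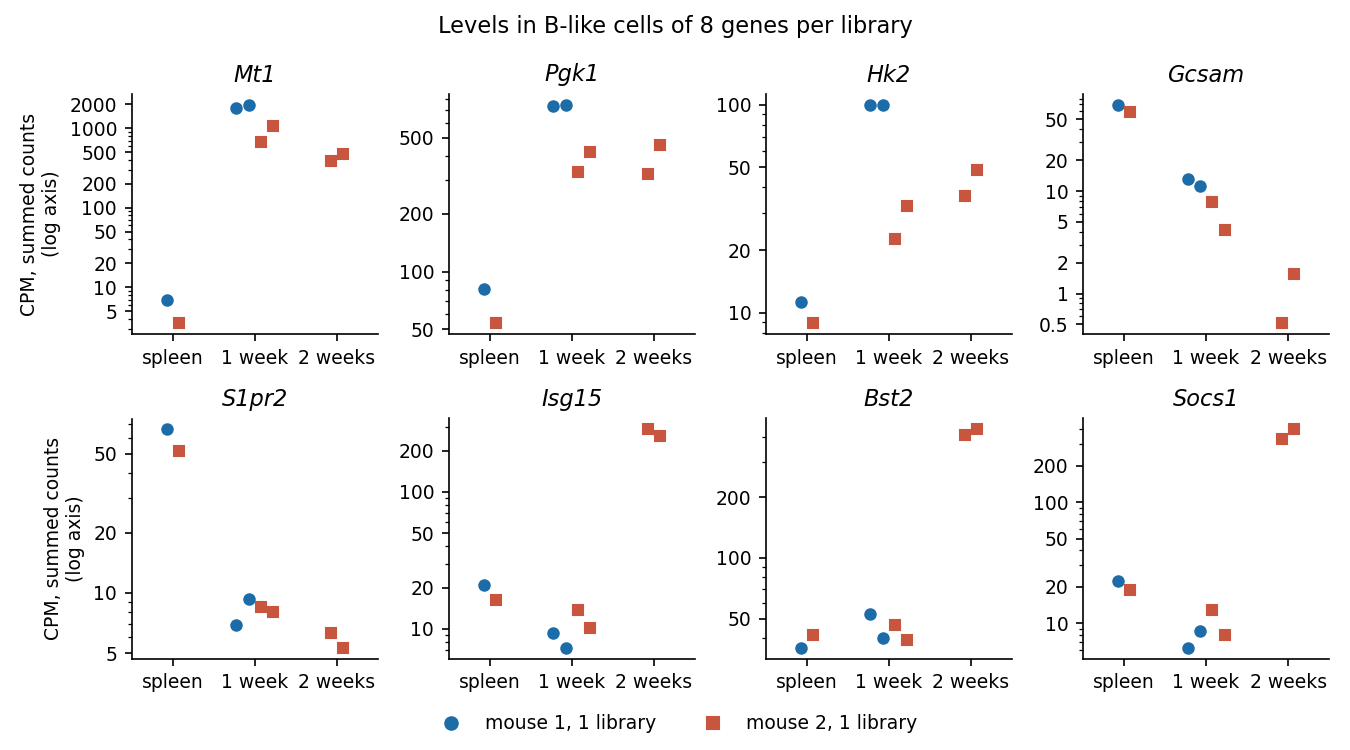
CPM (counts scaled to library size, vertical log axes) of 8 genes in the summed B-like cells of each library of the spleens, 1-week and 2-week explants; points are libraries, coloured by mouse. Pgk1 lies at 80.8 and 53.7 CPM in the spleens and at 325 to 744 CPM in the 6 explants, while Isg15 lies at 7.28 to 20.9 CPM in spleens and 1-week explants and at 286 and 254 CPM in the 2-week explants.

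Germinal centre genes fell in these cells, 13 of 15 tested and 15 adjusted over the list alone, with a median log2 change of -1.56. The list had an adjusted p = 6.39e-36, and an adjusted p = 0.0499 with an estimated correlation. Gcsam, which regulates motility of germinal centre B cells, changed by -2.90 (SE 0.21) and the confinement receptor S1pr2 by -2.78 (SE 0.16). The transcription factor Mef2b changed by -2.13 (SE 0.18). Bcl6, the main transcription factor of this state, was at -0.41 (SE 0.17) and did not pass the test (adjusted p = 0.12). Clusters held the class unequally. A cluster led by Cr2 and Serpinb1a made up 56.4% of spleen and 4.58% of 1-week B-like cells. Clusters led by Bank1 and Cd38 and by Egr3 and Nfkbid made up 12.9% and 2.42% of spleen B-like cells. They made up 58.0% and 26.0% of 1-week B-like cells, so values of the class compare largely different clusters. A cluster led by Rgs13 and Gcsam made up 26.5% of spleen and 9.99% of 1-week B-like cells. A small cluster with Gcsam among its leading genes held 32 and 1 cells at these stages. With both of these germinal centre clusters left out, a choice made after the data were seen, the median log2 change of the 13 called genes was -0.087 (SE 0.221) over the 11 still tested, against -1.68 with all cells. The clusters were picked for leading genes of this list, so these medians cannot tell fewer cells from lower levels within cells. In the 1-week explants the clusters differed by mouse. One led by Bank1, Cd38 and Ccr6 held 15.2% and 20.3% of the B-like cells in those of mouse 1 and 79.2% and 77.4% in those of mouse 2, and one led by Egr3, Nfkbid and Egr1 held 65.5% and 55.9% against 7.29% and 10.8%. In the spleens of mouse 1 and mouse 2 the former held 1.2% and 18.7%, so it differed there too, and the latter 2.76% and 2.26%. Of 14 tested genes of MHC class II presentation 9 fell, 10 adjusted over the list alone. This list had an adjusted p = 3.11e-08, and an adjusted p = 0.0499 with an estimated correlation. It included H2-Ab1 (-0.78, SE 0.08) and the transactivator Ciita (-0.98, SE 0.13), and the invariant chain Cd74 changed by -0.63 (SE 0.09).

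Other lists lost their call with an estimated correlation. By fry the adjusted p was 0.00628 for cholesterol synthesis, 0.0115 for the large ribosomal subunit and 0.0188 for mitochondrially encoded genes. It was 0.182 for type I interferon genes and 0.00628 for the regulatory T cell list. Of 23 cholesterol synthesis genes 12 fell, 14 adjusted over the list alone, including Cyp51 (-1.51, SE 0.20) and Fdps (-1.24, SE 0.17). The list had an adjusted p = 1.73e-06, and an adjusted p = 0.115 with an estimated correlation. Of 31 genes of the large ribosomal subunit 29 rose, 30 adjusted over the list alone, by a median log2 of 0.50 (adjusted p = 9.83e-17; adjusted p = 0.321 with an estimated correlation). Of 13 mitochondrially encoded genes 9 fell and 2 rose, the same adjusted over the list alone (adjusted p = 1.63e-06; adjusted p = 0.321 with an estimated correlation). Of 29 type I interferon genes 7 fell, 8 adjusted over the list alone. That list had an adjusted p = 0.00106, and an adjusted p = 0.556 with an estimated correlation. Of 10 genes of the regulatory T cell list 6 rose, 7 adjusted over the list alone (adjusted p = 3.26e-08; adjusted p = 0.0767 with an estimated correlation). Among them Il2ra, an interleukin-2 receptor chain that activated B cells also carry, had 3 counts in spleen and 169 in 1-week B-like cells, a ratio of 52.8 with a 95% counting interval of 17.8 to 258.5. Ctla4, an inhibitory receptor, rose by 3.66 (SE 0.33). Free RNA could give 40.8% of the level of this list's median member and 5.68% of that of Il2ra.

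Among genes with a mean log2 CPM of at least 5, those that fell included Fcer2a (-1.22), the low-affinity IgE receptor of follicular B cells, the transcription factor Klf2 (-1.10), Tsc22d3 (-1.41), the adaptor Scimp (-1.62) and Rgs13 (-1.44), a regulator of G-protein signalling. Emp3 (-1.42), Basp1 (-1.32), Adgre5 (-1.28), Dck (-1.18), Clec2d (-1.18), Smco4 (-1.17) and Mbd2 (-1.12) fell too, with SE between 0.11 and 0.20 over these 12 genes. Bcl2 changed by -0.36 (SE 0.10, adjusted p = 0.023; call lost in 6 of 23 alternatives), where reads of the transgene were not told apart from those of the mouse gene. Cd79a, a chain of the B-cell receptor, changed by -0.33 (SE 0.09, adjusted p = 0.026; call lost in 7 of 23). The proliferation marker Mki67 changed by -0.95 (SE 0.30, adjusted p = 0.045; call lost in 8 of 23), and by 0.38 with equal numbers of cells per library. In all, 1827 of 10710 genes changed at an adjusted p of 0.05, 933 up and 894 down, and 22 of 38 lists passed, 11 in each direction, of which 3 held with an estimated correlation. DESeq2 called 1168 genes, a fit without the mouse block 1073 and a fit on equal numbers of cells 671.

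Between 1 and 2 weeks, the interferon and MHC class II lists passed upward in B-like cells and the list of follicular and naive B-cell genes downward, and only the interferon gamma list among them held its call with an estimated correlation. By fry the adjusted p was 0.00196 for the type I interferon list and 0.000283 for the interferon gamma list. It was 0.000149 for MHC class II and 0.00786 for follicular and naive B-cell genes. All 29 tested genes of the type I interferon list rose, 29 adjusted over the list alone, with a median log2 change of 2.74. The list had an adjusted p = 1.28e-58, and an adjusted p = 0.055 with an estimated correlation. Among them were the ubiquitin-like modifier Isg15 (4.66, SE 0.19), the exonuclease Isg20 (3.55, SE 0.16) and Bst2, the virus-tethering protein tetherin (chromosome 8, 71534255 to 71537456, minus strand; 3.24, SE 0.14). All 29 genes of the interferon gamma list rose as well, 29 adjusted over the list alone, with a median of 1.32 (adjusted p = 6.34e-39; adjusted p = 0.0232 with an estimated correlation). They included the feedback inhibitor Socs1 (5.25, SE 0.20) and the GTPases Gbp2 (3.72, SE 0.23) and Igtp (2.88, SE 0.20). Free RNA could give 7.94% and 7.56% of the level of the median member of these lists. Of 14 MHC class II genes 11 rose and 1 fell, 12 and 1 adjusted over the list alone (adjusted p = 4.55e-08; adjusted p = 0.055 with an estimated correlation). H2-DMa (1.60, SE 0.10) and Cd74 (0.63, SE 0.11) were among those that rose.

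The lists that follow passed upward at 2 weeks and lost their call with an estimated correlation. Of 20 genes of the unfolded protein response 14 rose, 15 adjusted over the list alone (adjusted p = 1.17e-08; adjusted p = 0.154 with an estimated correlation). Xbp1, a transcription factor of this response and of plasma cells, rose by 2.02 (SE 0.14). Of 18 genes of the amino acid response 16 rose, 17 adjusted over the list alone, with Atf5 at 2.55 (SE 0.32). That list had an adjusted p = 7.19e-09, and an adjusted p = 0.055 with an estimated correlation. Of 19 p53 targets 14 rose and 1 fell, 15 and 1 adjusted over the list alone (adjusted p = 3.33e-08; adjusted p = 0.0965 with an estimated correlation). Phlda3 (4.18, SE 0.35), the cell cycle inhibitor Cdkn1a (3.12, SE 0.25) and the apoptosis effector Bax (1.48, SE 0.12) rose. Of 15 heat shock genes 14 rose, 15 adjusted over the list alone (adjusted p = 7.99e-08; adjusted p = 0.055 with an estimated correlation). The list of the oxidative stress response did not pass, where 9 rose and 2 fell of 21, 10 and 2 adjusted over the list alone (adjusted p = 0.0781; adjusted p = 0.412 with an estimated correlation). Of 25 S phase genes 16 rose, 20 adjusted over the list alone (adjusted p = 1.5e-05, adjusted p = 0.356 with an estimated correlation), such as Uhrf1 (1.68, SE 0.23). Uhrf1 was among the leading genes of a B-like cluster with a median of 33595.5 UMIs per cell. That cluster held 0.992% of 1-week and 3.19% of 2-week B-like cells, and its part in the rise was not tested. Of 15 genes of the macrophage lipid and repair list 11 rose and 2 fell, the same adjusted over the list alone (adjusted p = 3e-06; adjusted p = 0.165 with an estimated correlation). Free RNA could give 100% of the level of the median member of that list, and 100% for Chil3 and Spp1.

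Follicular and naive B-cell genes fell in 11 of 16 cases and rose in 2, 12 and 2 adjusted over the list alone (adjusted p = 1.21e-06; adjusted p = 0.154 with an estimated correlation). The complement receptor Cr2 changed by -3.05 (SE 0.21) and Fcrl1 by -2.07 (SE 0.15). Genes of B-cell receptor signalling fell in 14 of 26 cases and rose in 4, 15 and 4 adjusted over the list alone (adjusted p = 2.68e-05, adjusted p = 0.251 with an estimated correlation and adjusted p = 0.00613 by fry). They included the scaffold Bank1 (-1.85, SE 0.12) and the kinases Prkcb (-1.63, SE 0.13) and Syk (-1.60, SE 0.13). Among genes with a mean log2 CPM of at least 5, falls included those of Wfdc17 (-3.75), the chemokine receptor Ccr6 (-3.71), Cmah (-3.46), Serpinb1a (-2.83), Cd24a (-2.79), the egress receptor S1pr1 (-2.57), Id3 (-2.44), the integrin Itga4 (-2.42), Arhgef3 (-2.40), Arhgef18 (-2.35), Fcrla (-2.31) and Crip1 (-2.16). Rises above the same level included those of Klhdc2 (4.06), the amino acid oxidase Il4i1 (3.75), the nucleic acid sensor Zbp1 (3.57), Serpina3g (3.16), Samsn1 (2.91), Rnf19b (2.65), Pkib (2.54), Ifi47 (2.51), Gng12 (2.37), the activation marker Cd69 (2.32) and Syngr2 (2.31). Cd79a changed by -0.32 (SE 0.11, adjusted p = 0.032), a call that was lost in 10 of 22 alternatives. Bcl6 (0.13, adjusted p = 0.62), Bcl2 (-0.21, adjusted p = 0.17) and Mki67 (0.63, adjusted p = 0.17) did not pass the test.

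**Figure D3:**
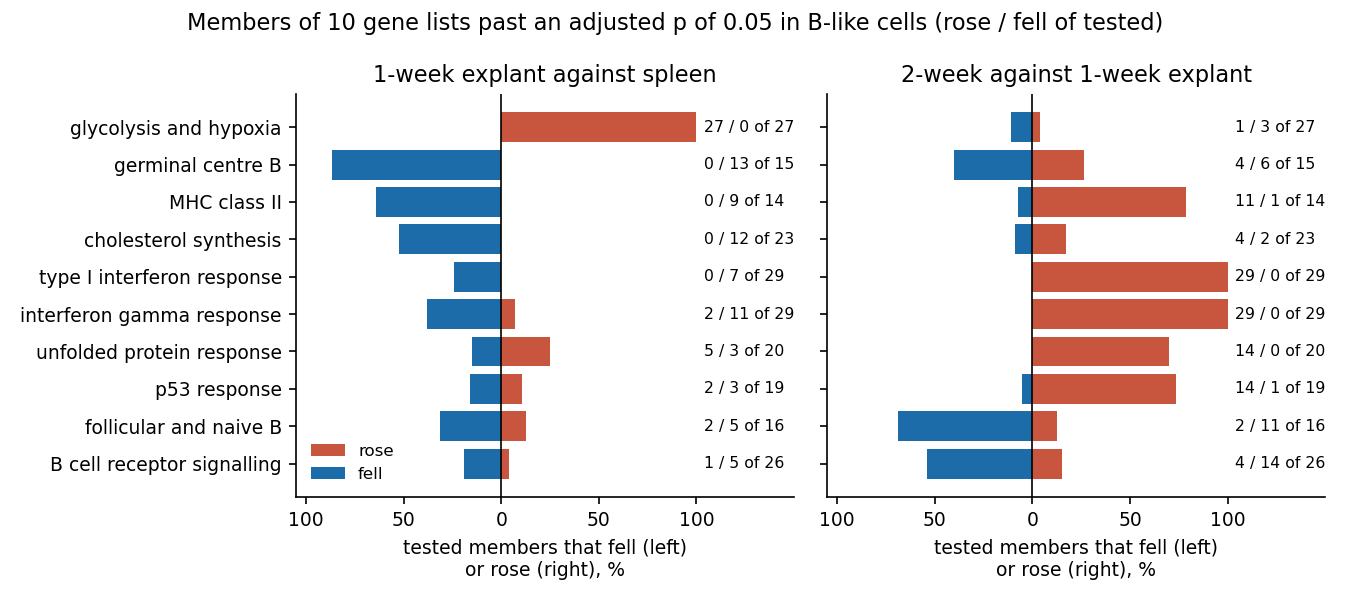
Percent of the tested members of 10 gene lists that fell (left of 0) or rose (right of 0) at an adjusted p of 0.05 in B-like cells, for 1-week explants against spleens and for 2-week against 1-week explants; the numbers beside the bars are genes that rose and fell of those tested. All 27 glycolysis and hypoxia genes rose in the first comparison, and all 29 genes of each interferon list rose in the second.

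For the glycolysis and hypoxia list, 1 gene rose and 3 fell of 27 at this step, the same adjusted over the list alone, and the list did not pass (adjusted p = 0.746). That test, with the mouse block, pointed down although the median change was 0.22. Without the mouse block the list passed (adjusted p = 0.03), in a direction that is not given here. In all 3629 of 10710 genes passed, 1942 up and 1687 down, and 22 of 38 lists, 17 up and 5 down, of which 1 held with an estimated correlation. Different clusters held the B-like class at these stages: at 2 weeks 56.7% of the cells lay in a cluster led by Il4i1 and Cd83 and 29.96% in a cluster led by Serpina3f and Gbp2. The 2-week libraries came from 1 mouse, and the count was 2231 and 2043 without the first or the second of them, 2342 with DESeq2 and 1757 with equal numbers of cells.

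Against the spleen, 4075 genes differed in 2-week B-like cells, 2140 up and 1935 down. Among genes with a mean log2 CPM of at least 5, metallothioneins again rose most, with Mt2 at 8.13 (SE 0.39) and Mt1 at 6.98 (SE 0.26). Klhdc2 (4.38), the growth arrest gene Gadd45g (4.07), Il4i1 (3.92), Bnip3 (3.71), Samsn1 (3.65), Bst2 (3.42), Syngr2 (3.25), the D-type cyclin Ccnd2 (3.18), Hilpda (3.07) and Zbp1 (3.06) followed. Falls above that level included those of Serpinb1a (-3.92), Cmah (-3.65), Ccr6 (-3.23), Crip1 (-2.99), Arhgef18 (-2.97), Fcrla (-2.96), March1, a ubiquitin ligase for MHC class II (-2.57), the complement regulator Cd55 (-2.57), S1pr1 (-2.53), Itga4 (-2.48), Atp2a3 (-2.41) and Id3 (-2.38). Bcl2 changed by -0.57 (SE 0.13, adjusted p = 0.0026) and Cd79a by -0.65 (SE 0.12, adjusted p = 0.0007). Mki67 (-0.32, adjusted p = 0.47), Bcl6 (-0.28, adjusted p = 0.29) and Cd74 (0.01, adjusted p = 0.98) did not pass the test. The count was 2487 without the second 2-week library, 2643 with DESeq2 and 1825 with equal numbers of cells.

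In T-like cells after 1 week, the glycolysis and hypoxia list passed upward and the type I interferon, follicular helper and cytotoxic lists downward, and all 4 lost their call with an estimated correlation. Of the 27 glycolysis and hypoxia genes 26 rose, 26 adjusted over the list alone, including Bnip3 (3.76, SE 0.26), Hk2 (3.52, SE 0.23) and Tpi1 (3.45, SE 0.18). The list had an adjusted p = 3.02e-108, and an adjusted p = 0.0543 with an estimated correlation. Mt2 rose by 7.09 (SE 0.29), Mt1 by 5.83 (SE 0.24) and Hilpda by 3.64 (SE 0.24). The transcription factors Fosl2 (3.91, SE 0.24) and Crem (3.01, SE 0.18) rose too. Of 29 type I interferon genes 17 fell, 20 adjusted over the list alone, such as Ifi27l2a (-1.33, SE 0.14) and the transcription factor Irf7 (-1.35, SE 0.21). That list had an adjusted p = 2.12e-17, and an adjusted p = 0.233 with an estimated correlation. Of 16 follicular helper genes 9 fell and 2 rose, 10 and 2 adjusted over the list alone (adjusted p = 5e-07; adjusted p = 0.0874 with an estimated correlation), with the folate receptor Izumo1r at -1.64 (SE 0.14). Of 16 cytotoxic genes 8 fell and 2 rose, 9 and 2 adjusted over the list alone (adjusted p = 0.000127; adjusted p = 0.109 with an estimated correlation), with the protease Ctsw at -1.53 (SE 0.18). The chemokine Ccl3 went from 511 counts in the spleens to 2 in the 1-week explants, a ratio of 204 with a 95% counting interval of 56.2 to 1689. S100a4 (-2.08), Id3 (-2.03), S100a6 (-1.96), Pycard (-1.56), Epsti1 (-1.52) and Nkg7 (-1.51) fell too. Spleen T-like cells lay in a cluster led by Dapl1 and Lef1 (64.5%) and one led by Tnfrsf4, Izumo1r and Foxp3 (34.7%), and 1-week cells in the same clusters (59.4% and 39.3%).

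B-lineage lists went both ways in T-like cells, where free RNA of B cells was high. Of 14 MHC class II genes 11 rose, 12 adjusted over the list alone (adjusted p = 7.21e-08; adjusted p = 0.361 with an estimated correlation). Of 11 heavy chain constant region and class switch genes 8 rose, 9 adjusted over the list alone (adjusted p = 4.62e-07; adjusted p = 0.248 with an estimated correlation). Free RNA could give 20.5% and 62.0% of the level of the median members of these 2 lists by the median of 3 marker sets. By the set of B-cell genes alone, which stood in T-like cells of the 1-week explants at 12.1% to 54.3% of their level in all cells, it could give 71.0% and 97.9%. Of 26 genes of B-cell receptor signalling 13 rose, while adjusted over the list alone 14 rose and 1 fell (adjusted p = 9.58e-06; adjusted p = 0.364 with an estimated correlation). Of 9 germinal centre genes 4 rose, 5 adjusted over the list alone (adjusted p = 0.00432; adjusted p = 0.361 with an estimated correlation). Of 7 genes of age-associated B cells 3 fell, 3 adjusted over the list alone (adjusted p = 0.0327; adjusted p = 0.364 with an estimated correlation). The follicular and naive B-cell list (adjusted p = 0.175) and the marginal zone list (adjusted p = 0.189) did not pass. H2-Aa went from 2.12 (SE 0.40) to -1.78 once cells with both B- and T-cell receptor transcripts were removed. In all 1001 of 9668 genes changed, 544 up and 457 down, and 16 of 38 lists passed, of which 0 held with an estimated correlation. The list tests in T-like and myeloid-like cells were added after the data were seen, on lists fixed earlier. The count of genes was 533 and 572 without the spleen of mouse 1 or mouse 2, 554 with DESeq2 and 423 with equal numbers of cells.

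Myeloid-like cells of the 1-week explants lay in other clusters than those of the spleen, so that the values below compare different populations. A cluster led by Thbs1, Cxcl2, Saa3 and Cxcl3 held 89.6% of them. Its best-scoring class was neutrophil, at only 0.192 against 0.061 for the best class outside the myeloid ones. Of its leading genes 0 were myeloid markers, so its name is weak. Spleen myeloid-like cells lay in clusters led by Vcam1 and C1qa (61.0%), by Ngp and Camp (20.4%) and by Ace and Cx3cr1 (16.8%). These scored best as macrophage (0.832), neutrophil (1.0) and monocyte (0.683). A change within macrophages cannot be read from the values below. Arg1 (arginase), Saa3 (an acute-phase protein), the chemokine Cxcl3 and Nos2 (nitric oxide synthase) had 0 counts in both spleens. They were at least 949-fold, 1137-fold, 450-fold and 113-fold higher in the explants, against a floor of 3 counts over both spleens. The protease Mmp12 (9.33, SE 0.94), Mt2 (6.65, SE 0.86), Gpnmb (6.55, SE 0.47), the oxygen-dependent prolyl hydroxylase Egln3 (6.47, SE 0.48) and Thbs1 (6.35, SE 0.77) rose. All 27 glycolysis and hypoxia genes rose, 27 adjusted over the list alone (adjusted p = 9.77e-47; adjusted p = 0.127 with an estimated correlation), including the angiogenic factor Vegfa (5.39, SE 0.29). Of 14 MHC class II genes 11 fell, 11 adjusted over the list alone (adjusted p = 9.1e-18; adjusted p = 0.127 with an estimated correlation). H2-Eb1 changed by -5.08 (SE 0.66), H2-Ab1 by -4.31 (SE 0.38), Cd74 by -4.17 (SE 0.30) and H2-Aa by -4.04 (SE 0.46). The neutrophil granule gene Camp (-3.91, SE 0.91), Hfe (-3.15, SE 0.22), the complement gene C1qb (-3.12, SE 0.84) and Pou2f2 (-2.80, SE 0.20) fell too, where the calls of Camp and C1qb were lost in 4 and 8 of 22 alternatives.

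Of 17 genes of the inflammatory macrophage list 10 rose in the myeloid-like class, 10 adjusted over the list alone (adjusted p = 6.41e-07; adjusted p = 0.275 with an estimated correlation). Most explant cells of this class lay in the weakly named cluster whose best class was neutrophil. Of 24 genes of the oxidative stress response 15 rose and 2 fell, 15 and 3 adjusted over the list alone (adjusted p = 5.28e-08; adjusted p = 0.335 with an estimated correlation), such as the cystine transporter Slc7a11 (3.82, SE 0.28). The lysosomal protease Ctsd (2.56, SE 0.27) was among 8 of 28 autophagy and lysosome genes that rose, where 2 fell, 10 and 2 adjusted over the list alone (adjusted p = 0.00128; adjusted p = 0.127 with an estimated correlation). In all 1446 of 9260 genes changed, 678 up and 768 down, and 17 of 38 lists, of which 0 held with an estimated correlation. The count was 865 without the 2-week explants, 536 without the spleen of mouse 2, 944 without the first 1-week explant of mouse 2, 901 and 905 without either 2-week explant and 465 with equal numbers of cells. On simulated counts 5.97% of 2-fold changes were recovered in this class.

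The mice differed in the size of the 1-week change of some genes in B-like cells. A test of the difference itself passed for 225 of 10710 genes, with 92 more positive and 133 more negative in mouse 2. Each mouse had 1 spleen library, so the spread in this test came from explant pairs of the same animal alone. It does not cover the spread between spleen libraries or between animals. Across these 10710 genes, which are not independent replicates, the log2 changes of mouse 1 and mouse 2 had a Pearson correlation of 0.570. The genes named here were chosen by smallest adjusted p after their values were seen. The survival gene Bcl2a1b differed by -2.29 on the log2 scale (mouse 2 minus mouse 1, SE 0.20), the chromatin organiser Satb1 by 1.69 (SE 0.18), Snrnp25 by -1.90 (SE 0.21), the cytokine receptor Il9r by -2.60 (SE 0.29) and Nfkbia, an inhibitor of NF-kB, by -1.41 (SE 0.16). Their adjusted p lay between 6.6e-05 and 0.0005. Bcl2a1b belongs to a family of near-identical copies, so its counts are uncertain. The count was 109 with DESeq2, 28 under 5% mitochondrial UMIs, 3 with equal numbers of cells, 118 without the first 1-week explant of mouse 2 and 125 without the second of mouse 1.

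Immunoglobulin V gene usage of the explants was compared with both spleens, to ask whether an explant held the repertoire of its own mouse. Similarity, as 1 minus the Bray-Curtis distance of V gene UMI shares, was higher to the mouse's own spleen than to the other spleen by a mean of 0.0913, with a positive value in 5 of 6 explants. The 1-week explants of mouse 2 gave 0.160 and 0.192 and its 2-week explants 0.149 and 0.0996. Those of mouse 1 gave 0.0246 and -0.0779, and the spleens had a similarity of 0.485 to each other. The spleens of mouse 1 and mouse 2 held 2724 and 8579 V gene UMIs, so they were compared at unlike depths. The pairs of 1-week explants of mouse 1 and mouse 2 had similarities of 0.359 and 0.382. Between the mice, 1-week explants had 0.265 to 0.399, highest for the second of mouse 1 with the first of mouse 2. The 2-week explants had 0.754 to each other. The light chain gene Igkv5-39 made up 17.0% of V gene UMIs in the first 1-week explant of mouse 2 and 6.52% in its spleen, but also 13.8% in the second explant of mouse 1, against 0.184% in the spleen of mouse 1. Igkv12-44 made up 12.1% and 13.9% in the explants of mouse 1 and 1.87% in its spleen. As the similarity to the spleen of mouse 2 minus that to the spleen of mouse 1, explants of mouse 1 averaged 0.0266 and those of mouse 2 averaged 0.1503. An exact two-sided permutation test over the 6 explants, chosen after the values were seen, gave p = 0.0667, the smallest that its 15 arrangements allow, and counts explants of 1 animal as separate. All of these values rest on the labels, and the second explant of mouse 1 was kept as labelled although its V gene usage was closer to the spleen of mouse 2. They pool B-like and plasma-like cells, so that a few plasma-like cells may dominate them. In that explant 24 plasma-like cells gave 33501 heavy chain constant region UMIs, against 7919 from 281 B-like cells. In the spleens 36 and 82 plasma-like cells gave 35771 and 108266, against 12203 and 19880 from B-like cells.

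The share of B-like cells with at least 2 UMIs of G2M phase genes was compared after thinning each cell to 2000 UMIs. It was 12.6% and 9.22% in the spleens and 14.8%, 10.1%, 6.75% and 6.44% in the 1-week explants, a mean difference of -1.38 points (exact permutation p = 0.444). Without thinning the difference was 19.5 points (exact permutation p = 0.111), at median depths in B-like cells of 3988 and 3940 UMIs in spleens and 7193 to 8159 in explants. In summed T-like cells 7 of the 25 G2M phase genes passed the expression filter, against 25 in B-like cells. The T-like share may thus rest on few genes and is not set against that of B-like cells. It also leaves out the granzyme-led clusters without a class name. In T-like cells, at median depths of 4166 to 4771 UMIs, the thinned share was 32.2% and 29.6% in the spleens and 21.9% to 28.8% in the 1-week explants. In the 2-week explants it was 4.35% and 5.76% of B-like cells and 16.1% and 11.3% of T-like cells, without a test. Levels of the G2M phase list in summed B-like cells went the other way from 1 to 2 weeks: 14 of 25 genes rose and 1 fell, 17 and 1 adjusted over the list alone, with a median log2 change of 1.12 (adjusted p = 0.00186; adjusted p = 0.513 with an estimated correlation). From spleen to 1 week 1 rose and 4 fell of 25, the same adjusted over the list alone, with a median of -0.55 (adjusted p = 0.0374; adjusted p = 0.738 with an estimated correlation). The thinned share counts each cell once, while summed counts weigh cells by their UMIs. A B-like cluster with Pclaf, Stmn1 and Top2a among its leading genes had a median of 33595.5 UMIs per cell. It held 0.992% of 1-week and 3.19% of 2-week B-like cells. Whether it gives the rise of the list was not tested, and in B-like cells the measures give no order of the stages.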

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

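The measures of libraries examined here and the test of all genes without a cluster were chosen after the data were seen. The other cluster test and that of cell numbers were written before the medians they measure were seen. By then the cluster's shares and the count with equal numbers of cells were already known. In the second 1-week explant of mouse 1, B-cell genes in T-like cells stood at 54.3% of their level in all cells, far from the other 1-week explants at 16.5%, 12.1% and 17.5%. Of 15 measures examined, mostly on the same 1-week explants, this was the 1 in which a library stood apart. Chance gives about 1 in 20 for each measure, so 1 among 15 may be chance. In that explant 8.74% of cells had transcripts of both B- and T-cell receptors, against 3.34% to 5.98% in the other 1-week explants. Its V gene usage was closer to the spleen of mouse 2 than to that of its own mouse (-0.0779), with Igkv5-39 at 13.8%, while Igkv12-44 was at 13.9% in it and 12.1% in the other 1-week explant of its mouse. A few plasma-like cells may dominate these V gene values. By clusters its B-like cells were nearer to the other 1-week explant of its mouse. The cluster led by Bank1, Cd38 and Ccr6 held 20.3% of them and 15.2% in that other explant. It held 79.2% and 77.4% in the 1-week explants of mouse 2. The cluster led by Egr3, Nfkbid and Egr1 held 55.9% and 65.5%, against 7.29% and 10.8%. A mixed or mislabelled library was not tested and stays open, and the comparisons between mice rest on this label.

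The 1-week change of B-like cells differed between the mice for 225 genes by a test of the difference itself. The spread in that test came from explant pairs of the same animal alone. A cluster led by Bank1, Cd38 and Ccr6 made up 15.2% and 20.3% of the B-like cells in the 1-week explants of mouse 1 and 79.2% and 77.4% in those of mouse 2. It differed in the spleens too, at 1.2% in mouse 1 and 18.7% in mouse 2. When all genes were tested again without that cluster 23 passed, 22 of them among the 225, which argues against the share of that cluster alone as the cause for these 22 and leaves it open for the others. The median difference of the 225 genes, turned to the sign it had with all cells, was 1.19 with the cluster and 0.89 (SE 0.281) without it, and with equal numbers of cells it was 1.06 (SE 0.428) with 205 of 218 signs kept, medians that decide nothing, since the genes were chosen for their difference in the same libraries. A cluster led by Egr3, Nfkbid and Egr1 made up 65.5% and 55.9% of the B-like cells in the 1-week explants of mouse 1 and 7.29% and 10.8% in those of mouse 2, and since it was not left out its share stays open for all 225 genes. Cell numbers stay open, as do the label of the explant above and a difference between the animals, which were not tested.

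Granzyme-led clusters that received no class name held 6.17% (95% interval 5.19 to 7.27) and 5.98% (5.01 to 7.07) of the cells of the 2-week explants. They held 0.117% and 0.131% of the spleens. In the 1-week explants they held 0 of 368 cells, which allows 0.815%, 0 of 469, which allows 0.640%, 0 of 1119, which allows 0.268%, and 0.152% of 659 cells. Their best-scoring class was T, at 0.696 and 0.617 against 0.045 and 0.043 for the next, with Cd3e in 92.1% and 92.3% of cells. They stayed unnamed because 1 leading gene was a marker of another class and 0 were T-cell markers. The T-like class and its shares leave them out.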

How the results depend on the processing

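Alternatives named as added in the account of the processing were chosen after the data were seen. Apart from leaving out libraries, 100 values of the compared results stayed the same, 19 moved and 7 changed sign. With each library left out, 80 stayed the same, 15 moved and 3 changed sign. Same means within 1.5 times for counts of genes and lists, the same sign for share differences, of which none has a p below 0.05, and within 1 SD between libraries for the others. For the named genes, 2269 values were unchanged in direction and call, 30 lost their call, 4 gained one and 2 changed sign. With each library left out, 1264 were unchanged, 27 lost their call, 3 gained one and 0 changed sign. The cause of a change was not tested unless it is given. The B-like share difference became 19.4 under 5% mitochondrial UMIs, 1.10 at resolution 2.0, 3.75 with a class per cell, 3.34 with the first naming score and 0.63 with co-expressing cells removed. With a class per cell the myeloid-like difference became 1.18. The plasma-like share difference, whose alternatives were all added later and are not in these counts, kept its sign, from 4.36 to 5.86 and from 3.26 to 8.05 with each library left out. The G2M difference became 19.5 unthinned, where depth differs between stages. DESeq2 called 1168, 2342 and 2643 genes in the 3 B-like comparisons (1-week against spleen, 2-week against 1-week, 2-week against spleen), 554 in T-like cells and 109 for the difference between mice. With equal numbers of cells, so fewer cells, the counts were 671, 1757, 1825, 423 (T-like), 465 (myeloid-like) and 3 (between mice). The latter was 464 with no low-count filter and 28 under 5% mitochondrial UMIs, and the myeloid-like count was 865 without the 2-week explants. With an estimated correlation 3 and 1 lists passed. The correlation between mice was 0.444 by Spearman's method and 0.703 for genes with a mean log2 CPM of at least 5.

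Without the mouse block (no pairing of libraries by mouse) the B-like 1-week count was 1073, the other B-like counts 2817 and 2967, the T-like 674, the myeloid-like 1452 and the lists 16 and 23. Of these, only the first differs by over 1.5 times from the reported count. The difference between mice needs the mice as terms.

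With each library left out in turn, the B-like share difference ran from -4.76 to 3.49, the T-like from 3.00 to 7.48, the myeloid-like from -5.36 to -0.204 and the G2M difference from -2.63 to -0.132. Counts ran from 1425 to 1748, 2043 to 4430 and 2487 to 4306 in B-like cells, the latter lows without the second 2-week explant and 2231 without the first. T-like counts ran from 533 to 948, with 533 and 572 without the spleen of mouse 1 or mouse 2. Myeloid-like counts ran from 536 to 1468, with 536 without the spleen of mouse 2, 944 without its first 1-week explant and 901 and 905 without either 2-week explant. The difference between mice ran from 118 to 235, with 118 without the first 1-week explant of mouse 2 and 125 without the second of mouse 1, and it could not be fitted without a spleen. Lists ran from 16 to 22 and 21 to 24, and the correlation from 0.525 to 0.539, below the 0.570 with all libraries. Where a stage keeps 1 library of a mouse, it is assumed to vary like the others.

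Among named genes, Mki67 in B-like cells at 1 week became 0.38 with equal numbers of cells, and H2-Aa in T-like cells became -1.78 with co-expressing cells removed. Calls of Bcl2, Cd79a and Mki67 at 1 week were lost in 6, 7 and 8 of 23 alternatives (adjusted p up to 0.198, 0.309 and 0.963) and that of Cd79a from 1 to 2 weeks in 10 of 22 (up to 0.237). Calls of C1qb and Camp in myeloid-like cells and H2-Aa in T-like cells were lost in 8, 4 and 3 of 22 (up to 0.228, 0.269 and 0.353). No alternatives were run for plasma-like genes or isotypes. V gene similarity stayed between 0.0659 and 0.116. In myeloid-like cells 5.97% of simulated 2-fold changes were recovered, at a coefficient of variation between libraries of 0.215, against 0.113 in T-like and 0.106 in B-like cells.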

Other observations

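The tests of plasma-like cells, that of free RNA for the hypoxia genes, that without 2 clusters and the look at isotype shares were chosen after the result was seen, and those of the germinal centre-led cluster and the mitochondrial limit when counts of calls under both, but not the medians, were known. Plasma-like cells of the 1-week explants had higher levels of Mt2 (3.37, SE 0.40), the cell cycle inhibitor Cdkn1a (3.07), the inhibitory receptor Lag3 (2.66, SE 0.20), Tpi1 (2.46) and Mif (2.40) on the log2 scale than those of the spleens. Eaf2 (-2.36, SE 0.17), Trf (-2.31) and the folding enzyme Txndc5 (-1.44, SE 0.15) were lower. In all 223 of 6975 genes changed by edgeR's test, 97 up and 126 down. Of 26 glycolysis and hypoxia genes 14 rose, 22 adjusted over the list alone (adjusted p = 1.02e-31; adjusted p = 0.172 with an estimated correlation). Of 16 genes of the plasma cell programme 6 fell, while adjusted over the list alone 7 fell and 1 rose (adjusted p = 1.08e-05; adjusted p = 0.264 with an estimated correlation), among them Jchain (-1.30) and Sdc1 (-1.22). From 1 to 2 weeks 215 genes changed, 122 up and 93 down, with Isg15 (4.09, SE 0.87), Vpreb3 (3.24, SE 0.46), Ifi27l2a (2.82, SE 0.23) and Bst2 (2.19) higher and Cd38 (-1.97, SE 0.24) lower. On simulated counts for the 1-week comparison, over 6975 genes, 0, 19.4% and 69.7% of 1.5-, 2- and 4-fold changes were recovered, and from 1 to 2 weeks 2.99%, 29.9% and 87.9%.

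Ighm, the constant region of IgM, made up 51.8% and 61.7% of the heavy chain constant region UMIs of B-like cells in the spleens and 73.2% to 81.0% in the 6 explants. In plasma-like cells it made up 46.0% and 49.0% in the spleens and 58.6% to 75.0% in the explants. Ighg2b made up 29.8% and 23.1% of them in spleen plasma-like cells and 1.62% to 18.5% in explants. These shares have no test.

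The fall of germinal centre genes in B-like cells at 1 week went with fewer cells of 2 clusters: one led by Rgs13 and Gcsam, 26.5% of the class in spleens and 9.99% in 1-week explants, and a small one led by H1fx, Pclaf and Stmn1, with Gcsam among its leading genes, 32 and 1 cells. With the first left out the 13 called genes had a median log2 change of -1.13 (SE 0.274), against -1.68 with all cells, and 11 of them were still called, which argues against the loss of that cluster alone as the whole cause. With both left out the median was -0.087 (SE 0.221) over the 11 genes still tested, 1 of them called, which met the prediction for a loss of such cells. It cannot decide the cause, since the clusters were picked for leading genes of this same list. It also covers fewer genes than the median of -1.68. Over all 15 tested genes of the list the median was -1.56, -1.03 (SE 0.247) without the first cluster and 0.049 (SE 0.214) over 13 genes without both, and free RNA could give 1.25% of the level of the median called gene. Cells that lost these transcripts would leave the clusters too, so lower levels within cells stay open, as does an effect of culture, which was not tested.

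The rise of glycolysis and hypoxia genes may come from free RNA, from the cells that the mitochondrial limit keeps, or from culture. Free RNA could give 8.04% of the level of the median gene, which argues against it as the cause. Under 5% mitochondrial UMIs the median log2 change was 1.98 (SE 0.210), against 2.02, and 26 of 27 genes were called, which argues against the limit. A response to culture is a hypothesis that was not tested.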
